A study of Glycine max with 19 samples.

How the data were processed

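Genomic DNA of leaf from 19 soybean (Glycine max) lines mutagenised with fast neutrons was hybridised to oligonucleotide arrays together with DNA of the wild type parent, M92-220-Long. Per the labels, the line carried Cy3 and the parent Cy5 on each array, with no exchange of dyes, and 500 ng of DNA was labelled. Each line was measured on 1 array, so there were no replicates and no p-value was given for any region of any line. The error given with a region is the standard error (SE) over its probes on that array, and beside it stand the mean and standard deviation (SD) of the same probes over the other 18 lines. The SE covers the spread between probes of 1 hybridisation and leaves out differences between plants, extractions and arrays.

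Per the file headers, the deposited scanner files were written by Agilent Feature Extraction version 12.0.0.7, and 8 arrays were read on a NimbleGen MS 200 scanner and 11 on an Agilent G2505C scanner, the latter in 2 periods of 7 and 4 arrays. The processed intensity of each channel in the deposited files is background-subtracted and dye-normalized with a linear factor, per the file headers, which give a lowess factor of 0 on every array. The deposited log10 ratio of red over green equalled the ratio of the processed intensities to within 0.001 in all but 0.194% to 0.335% of spots per array. The deposited series value table, whose scale, centring and direction are not given in the sources used here, was set against each array: its log2 values fell on a line with slope -1 against log2 of red over green, so they run as line over parent on the log2 scale. A constant between -0.00102 and 0.0606 had been added per array, and the origin of that constant stays unknown. The medians of its columns were 0.00033 for FNMN0001, -0.0033 for FNMN0005, 0.00046 for FNMN0008, 0.02 for FNMN0014, 0.06 for FNMN0016, 0.02 for FNMN0022, -0.0015 for FNMN0027, 0.04 for FNMN0030, -0.0025 for FNMN0036, 0.04 for FNMN0039, 0.04 for FNMN0041, 0.02 for FNMN0046, 0.02 for FNMN0048, 0.04 for FNMN0061, 0.02 for FNMN0065, 0.04 for FNMN0066, 0.02 for FNMN0069, 0.03 for FNMN0077 and 0.02 for FNMN0085.

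Each array held 960745 spots other than controls, for 951615 distinct probes on 20 chromosomes with a median spacing of 474 bp. Coordinates are those of the array design, whose name carries Gmax genome 275 of Phytozome 10; the header gives no build. A group of 8054 probes named Chr014 was placed on chromosome 14, because the 999 of them that lie inside a chromosome 14 deletion of FNMN0065 had a median log2 ratio of -5.92 there against -0.01 outside; the series value table holds no values for these probes. The gene table at hand belongs to another assembly of soybean, so genes were not placed on these coordinates, regions alone are named, and the planned comparison of gene lists with deletions was not run.

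The log2 ratio of line over parent was taken from the processed intensities, spots marked as outliers were left out (131 to 743 per array), spots of one probe were averaged, and each array was centred on its median without loess or quantile normalization. Between 98.8% and 99.5% of spots lay well above background in the line channel and between 99.2% and 99.4% in the parent channel, and at most 0.015% were saturated. The number of arrays, 1 per line, limits the precision. Values were limited to within 1 log2 unit of a running median of 9 probes, and change points were found on each chromosome by penalised least squares (PELT) with a penalty of 4 times the squared noise times the natural log of the number of probes. Neighbouring pieces between change points that each had a mean at or below -0.4 were joined into a run and called a lost segment where the run had at least 5 probes; gained segments were formed in the same way from pieces at or above 0.3. Homozygous-range segments were formed separately, from pieces at or below -1.5, since the loss of 1 copy of 2 gives at most -1. They lie inside lost segments, and 1 lost segment can hold several of them, where short patches above -1.5 lie between. A segment was private where no segment of the same kind in another line overlapped it by 50% or more of both lengths. The regions to be named were fixed before the data were examined: per line the largest homozygous-range loss, the largest other loss, meaning a lost segment without a homozygous-range segment in it, and the largest gain that at most 2 lines carried, and every segment of 1 Mb or more.

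Because short patches broke long events into many segments, a pair of summaries was added after seeing the data. Large events were runs of at least 1 Mb in medians of 100 kb bins, with the median of the other 18 lines subtracted, a mean at least 0.25 from 0 and gaps of up to 500 kb joined. Homozygous-range segments of one line were joined across gaps of up to 100 kb. Other regions named below were chosen after their values were seen.

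Alternatives planned before the data were examined were normexp background correction, the series value table, a filter on dim probes, a minimum of 10 or 3 probes, stricter limits (-0.6, 0.45 and -2) and looser limits (-0.3, 0.2 and -1.2), subtraction of each probe's median over the other arrays, a hidden Markov model, a doubled penalty and loess within arrays. The files used here give median and not mean signals, so normexp was run on median and background signals, with an offset of 50. Correlations over lines were tested by two-sided permutation tests with 100000 resamples, and the likeness of 1 pair of lines by its rank among all pairs, an exact one-sided test. P-values were adjusted by the method of Benjamini and Hochberg over the 3 relations tested.

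The segmentation was tested on simulated data made from each array's noise and smoothed baseline. Implants held 5 to 200 probes and were set at -0.85 for 1 lost copy, 0.55 for 1 gained copy and -5 for both lost. Changes nearer to the call limits and breaks within longer events were not simulated for the segmentation. The simulation of large events used the same 1-copy levels. Of 76 implanted gains of 1 copy with 5 probes 74 were recovered, as were 76 of 76 losses of 1 copy and 71 of 76 losses of both copies of that size; all implants of 10 or more probes were recovered, with 0 false calls on the 19 simulated arrays of 951615 probes. The smoothed baseline holds none of the short irregular patches of the real arrays, so that count of false calls is a lower limit. In a separate simulation of large events all 19 implants of each kind and of 1.5 and 3 Mb were recovered, with 0 false events elsewhere and 11 further events in stretches where the real array held one, whose remainder was still in the baseline. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and R 4.3.3 with limma 3.58.1.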

Results

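Copy number along the soybean genome was measured in 19 fast-neutron lines, named by their FNMN codes, each against the wild type parent M92-220-Long. Fast neutrons break DNA and can delete, duplicate or rearrange long stretches of chromosomes. Each line was represented by 1 array, so every value below describes that hybridisation and none has a replicate. The noise per probe, from differences between neighbouring probes, lay between 0.10 and 0.12 log2 units on all 19 arrays. With 2 copies in the parent, 1 copy would give a log2 ratio of -1, 3 copies a ratio of 0.58 and 4 copies a ratio of 1.

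The first question was which long stretches each line had lost or gained relative to its parent. In 12 of the 19 lines, 26 events of at least 1 Mb were found, 19 losses and 7 gains, covering 224 Mb when summed over lines; without FNMN0077, 19 events, 4 of them gains, and 122 Mb were left. FNMN0065 had the most sequence in homozygous-range losses, 18.9 Mb or 1.99% of the genome, and FNMN0077 had the most gained sequence, 86.3 Mb or 9.10%. FNMN0001, FNMN0005, FNMN0016, FNMN0022, FNMN0036, FNMN0046 and FNMN0069 had no event of this length.

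In 5 lines, 8 of these losses had levels between -5.60 and -4.37, below anything the removal of a single copy can give. FNMN0065 carried 3 of them. Its Chr14 loss from 24.9 to 36.3 Mb had a median of -5.60 ± 0.028 (SE over 6047 probes), against 0.05 ± 0.03 (SD, n = 18) in the other lines. Its Chr12 loss from 22.9 to 31.1 Mb lay at -5.10 ± 0.049 (SE over 2371 probes), against 0.07 ± 0.04 (SD, n = 18), and its Chr17 loss from 16.4 to 17.4 Mb at -4.37 ± 0.18. FNMN0030 had lost Chr06 from 37.6 to 45.5 Mb, with a median of -5.50 ± 0.026 (SE over 6099 probes) against 0.03 ± 0.02 (SD, n = 18). FNMN0048 had lost Chr03 from 19.5 to 21.9 Mb at -5.57 ± 0.087, and FNMN0014 had lost Chr10 from 35.3 to 36.5 Mb at -5.06 ± 0.073. FNMN0008 had 2 such losses on Chr04, from 7.1 to 8.1 Mb at -5.55 ± 0.057 and from 21.5 to 22.8 Mb at -5.05 ± 0.15. How far below -1 these levels lie depends on how background is handled: with normexp the 8 medians lay between -2.34 and -1.41.

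In 5 lines, 9 long losses lay between -0.91 and -0.82, close to the level of 1 lost copy. FNMN0027 had lost Chr06 from 19 to 21 Mb at -0.91 ± 0.0057 (SE over 1900 probes), against 0.03 ± 0.02 (SD, n = 18) elsewhere, and Chr03 from 8.9 to 10.7 Mb at -0.87 ± 0.011. FNMN0039 had lost Chr15 from 16.1 to 18.4 Mb at -0.90 ± 0.0067. In FNMN0061 a loss on Chr10 from 21.3 to 34 Mb lay at -0.82 ± 0.018, and inside it the stretch from 31322872 to 32441965 fell to -5.26 ± 0.082 (SE over 636 probes). FNMN0077 carried 4 such losses: Chr04 from 20.8 to 25.1 Mb at -0.83, Chr10 from 23.8 to 25.9 Mb at -0.85, the first 3.1 Mb of Chr13 at -0.89 and Chr14 from 20.1 to 24.4 Mb at -0.87, each with an SE of at most 0.0091. A further loss in FNMN0041, on Chr09, was shallower than these, at -0.36 ± 0.0037 from 14.2 to 19.7 Mb and -0.39 ± 0.0039 from 20.3 to 23.5 Mb, against 0.05 ± 0.03 and 0.04 ± 0.03 (SD, n = 18). A stretch too short for the list of long events, from 12.9 to 13.5 Mb, lay at -0.38 ± 0.0075 (SE over 387 probes), while FNMN0041 stood at 0.10 ± 0.017 from 13.5 to 14.1 Mb and at 0.04 ± 0.0095 from 19.7 to 20.3 Mb.

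**Figure D1:**
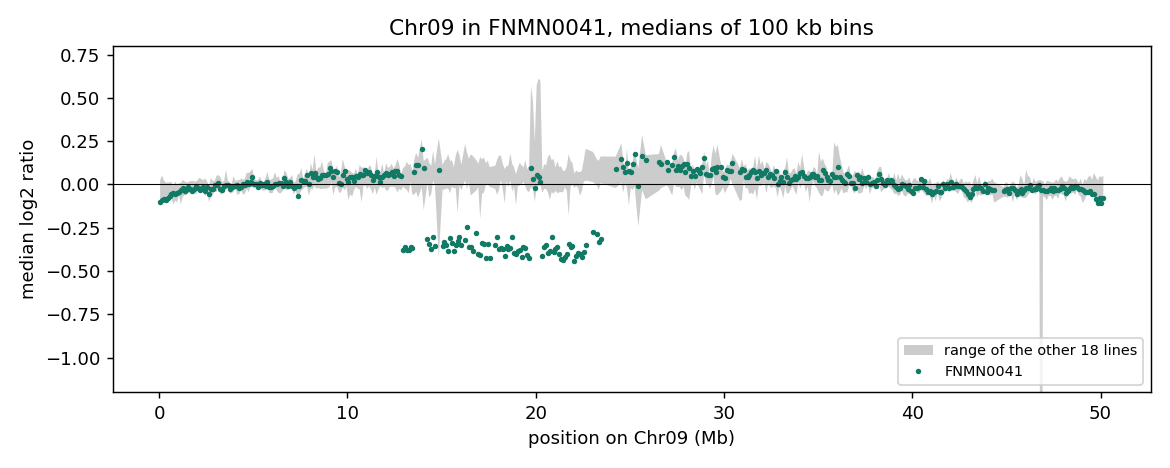
Medians of 100 kb bins (vertical axis, log2 ratio of line over parent) along Chr09 (horizontal axis, Mb) for FNMN0041, with the range of the other 18 lines in grey. The grey range reaches up to 0.61 between 19.7 and 20.3 Mb. The vertical axis ends above the lowest grey values, at the Chr09 loss of FNMN0039 from 46816063 to 46879003; the loss of FNMN0041 lies at -0.38 from 12.9 to 13.5 Mb, at -0.36 from 14.2 to 19.7 Mb and at -0.39 from 20.3 to 23.5 Mb, with values near 0 between these stretches.

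Long gains were found in FNMN0066, FNMN0077 and FNMN0085. The whole of Chr19 was raised in FNMN0077, with a chromosome median of 0.53, while the other 18 lines lay at 0.0038 ± 0.0027 (SD, n = 18). FNMN0077 also had a gain on Chr04 from 47 to 48.5 Mb at 0.51 ± 0.0030 (SE over 2533 probes). In FNMN0085, Chr06 from 6.4 to 11.5 Mb stood at 0.91 ± 0.0019 (SE over 9000 probes), against -0.03 ± 0.02 (SD, n = 18), higher than the 6 other long gains, which lay between 0.51 and 0.59. Of the 380 chromosome medians, 3 exceeded 0.2, and the rest lay between -0.04 and 0.03.

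**Figure D2:**
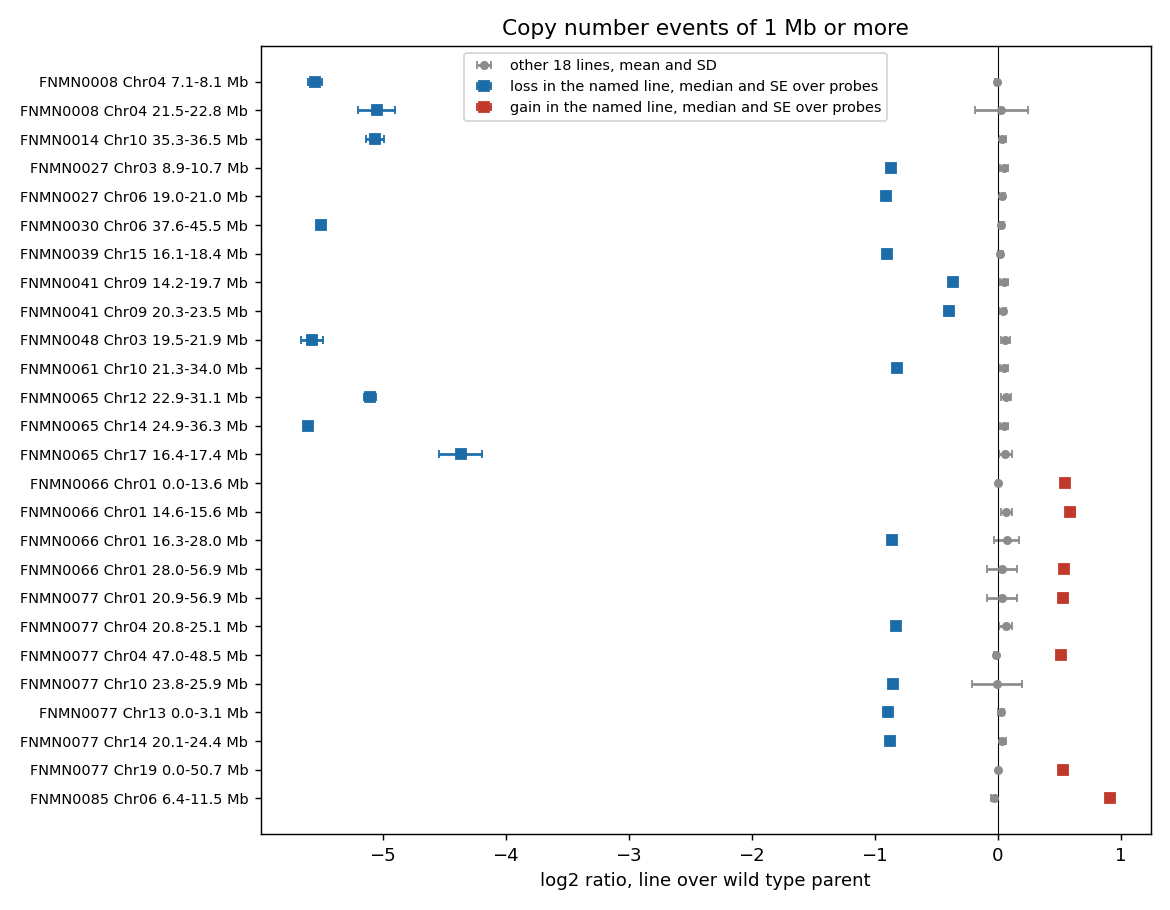
Median log2 ratio of line over parent (horizontal axis) of each event of at least 1 Mb (1 row per event, labelled with line, chromosome and position). Squares give the named line with its SE over probes and grey circles the mean and SD of the other 18 lines; losses fall into a group between -5.60 and -4.37 and a group between -0.91 and -0.82, with the Chr09 loss of FNMN0041 at -0.36 and -0.39.

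Chr01 was changed along much of its length in FNMN0066 and FNMN0077. In FNMN0066 it was gained from its start to 13.6 Mb at 0.54 ± 0.0013 (SE over 14667 probes) and from 28 to 56.9 Mb at 0.54 ± 0.0011 (SE over 28397 probes), while the stretch from 16.3 to 28 Mb was lost at -0.86 ± 0.0032 (SE over 5523 probes). Between 13.6 and 16.3 Mb lay a shorter loss from 13.7 to 14.6 Mb at -0.83 ± 0.014 (SE over 310 probes) and a short gain from 14.6 to 15.6 Mb at 0.59 ± 0.037, so that gains and losses alternated along this chromosome. In FNMN0077 the gain ran from 20.9 to 56.9 Mb at 0.53 ± 0.0011 (SE over 32220 probes). From 20.9 to 28 Mb the lines therefore moved apart, with FNMN0066 at -0.87 and FNMN0077 at 0.56 over 3823 probes.

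**Figure D3:**
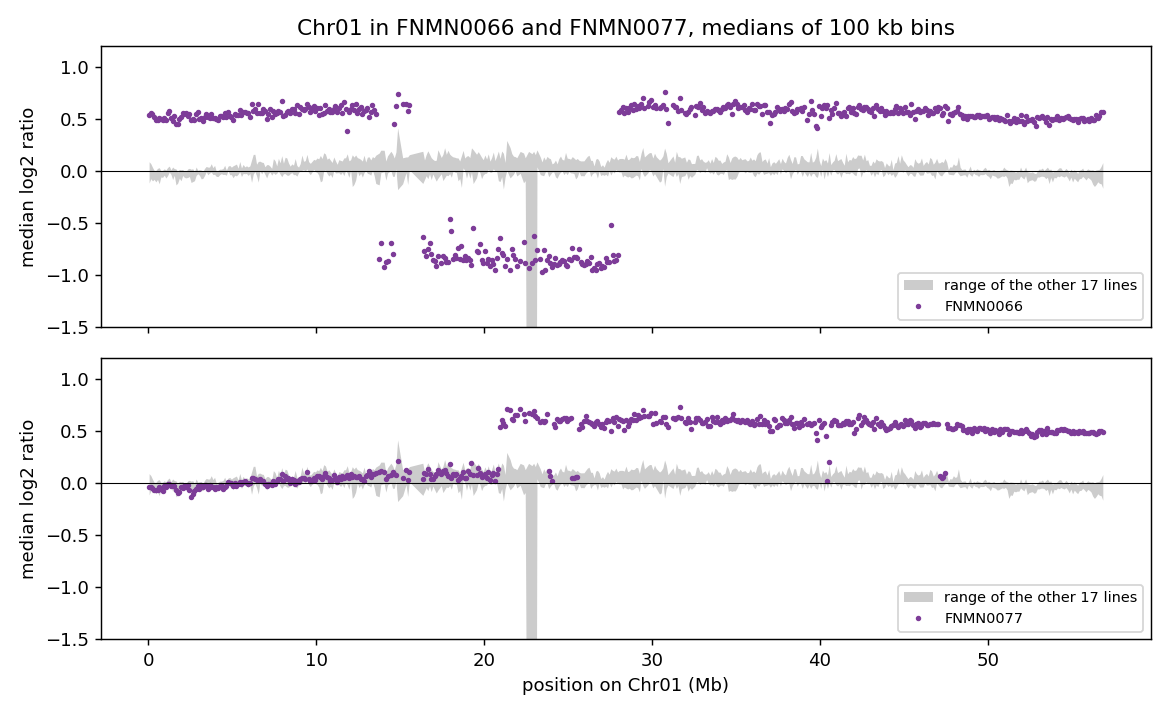
Medians of 100 kb bins (vertical axis, log2 ratio of line over parent) along Chr01 (horizontal axis, Mb) for FNMN0066 and FNMN0077, with the range of the other 17 lines in grey. The vertical axis ends above the lowest grey values, at the Chr01 loss of FNMN0022; FNMN0066 is gained at both ends and from 14.6 to 15.6 Mb and lost from 13.7 to 14.6 Mb and from 16.3 to 28 Mb, and FNMN0077 is gained from 20.9 Mb on.

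Shorter losses in the homozygous range were found in most lines. FNMN0001 had lost Chr07 from 3801319 to 4084517 at -5.95 ± 0.095 (SE over 493 probes), against -0.03 ± 0.02 (SD, n = 18). FNMN0022 had lost Chr01 from 22659709 to 23060449 at -5.67 ± 0.17, FNMN0036 Chr04 from 50431518 to 50569153 at -5.61 ± 0.13, FNMN0046 Chr10 from 44814671 to 45067748 at -5.98 ± 0.12 and FNMN0085 Chr13 from 32702923 to 32899469 at -5.53 ± 0.13. FNMN0048 had also lost Chr02 from 41284955 to 41689039 at -6.03 ± 0.083, and FNMN0061 Chr16 from 26493903 to 26992124 at -5.39 ± 0.097. FNMN0041 had lost Chr16 from 19454942 to 20197250 at -5.60 ± 0.11 and Chr11 from 28816615 to 29450316 at -4.83 ± 0.11. FNMN0065 had lost Chr19 from 45062002 to 45215324 at -5.90 ± 0.13 and Chr12 from 7370799 to 7564105 at -5.87 ± 0.12. FNMN0027 was the only one of the 19 lines with 0 homozygous-range segments.

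After joining, the 19 lines held 93 homozygous-range losses, with a median of 5 per line. At 52 of them no other line had a median at or below -1.5 over the whole loss. Shorter losses of other lines can still lie inside these 52. FNMN0061 stood at -5.74 from 27365909 to 27486803, inside the Chr14 loss of FNMN0065. FNMN0069 stood at -1.75 from 42996575 to 43002502, inside a Chr06 loss of FNMN0030. Of the 93, 34 lay at 8 of the 9 short loci where a loss was called in 18 or 19 lines, among them all those of FNMN0005 and FNMN0016; without these loci the median was 2 per line. FNMN0005, FNMN0016 and FNMN0027 had 0 of the 52. Inside the 52 losses 57.4% of the 23678 probes were not well above background in the line channel, so their levels depend on the handling of background. Requiring 10 probes per segment lowered the 93 to 59.

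Among the smaller losses of 1 copy and the smaller gains, FNMN0069 had lost Chr07 from 37595214 to 37918651 at a mean of -0.91 ± 0.0087 (SE over 506 probes). FNMN0061 had gained Chr02 from 25689589 to 25858105 at 0.97 ± 0.019 (SE over 128 probes), and FNMN0005 had gained Chr06 from 45886669 to 45903717 at 0.98 ± 0.032 (SE over 27 probes). FNMN0027 had gained Chr19 from 2235653 to 2443994 at 0.56 ± 0.0079 (SE over 325 probes). By the rule fixed beforehand, 16 largest homozygous-range losses, 19 largest other losses and 19 largest gains were named, and 16, 12 and 9 of them lay more than 3 SD from the other lines. A region inside that spread was the largest gain of FNMN0016, Chr19 from 18463587 to 18688824. It stood at 0.40 ± 0.040 over 13 probes against 0.31 ± 0.16 (SD, n = 18). All regions named by this rule were called in at most 2 lines, so some distance from the other lines comes with the choice. The named line's value was a mean of limited values, while each other line gave a median over the probes.

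Over all lines, 1092 segments were called lost and 685 gained. Inside 99 of the 1092 lost segments lay 253 homozygous-range segments, up to 28 in 1 lost segment. Of the lost and gained segments 48 were at least 1 Mb long, 21 of them in FNMN0077 and 13 in FNMN0066, where the Chr01 and Chr19 gains were broken into pieces; without FNMN0077 27 were left. Of the 1777 lost and gained segments 762 were private to one line. Among these were 60 lost and 92 gained segments of FNMN0066 and 59 lost and 63 gained segments of FNMN0077. Pieces of a long gain that both lines carried on Chr01 could count as private where their ends differed, so 762 is not a number of separate changes. Short losses and gains recurred: overlapping segments of the same kind were merged into loci, and of the loci of at most 100 kb 218 of 361 with a loss and 116 of 215 with a gain were called in 1 line, and 40 and 24 in 5 or more. Losses and gains were merged apart, and many of the recurring short losses overlapped a recurring gain. Chr18 from 18253491 to 18269187 was called lost in 4 lines, with levels from -0.68 to 0.30. An overlapping stretch from 18256525 to 18280190 was called gained in 4. Chr20 from 24599491 to 24615697 was called lost in 4 lines and gained in 5, with levels from -0.67 to 0.33. Chr20 from 42697443 to 42698976 was called lost in 4 lines and gained in 2, with levels from -0.69 to 0.81. Whether such short calls are copy number differences of the lines was not tested. A locus on Chr13 from 38797083 to 38859189 was lost at -1.52 ± 0.014 in FNMN0022, -1.55 ± 0.013 in FNMN0048 and -0.53 ± 0.010 in FNMN0027, with the same 2 end probes in all 3 lines. Scan period moved with the counts: the median number of lost segments per line was 40 on the 8 NimbleGen arrays, 50 on the first 7 Agilent arrays and 109 on the last 4 Agilent arrays, which held FNMN0046, FNMN0066, FNMN0077 and FNMN0085; each line was scanned in 1 period, so line and period cannot be told apart. None of the counts of lost, gained, homozygous-range and private segments held under every alternative: lost segments numbered from 475 to 2254, gained from 284 to 1410 and homozygous-range from 95 to 911. The share of gains among lost and gained segments, 38.5% here, ran from 27.5% with normexp to 47.5% with loess.

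FNMN0014 and FNMN0016 carry titles with a shared stem, and the share of called sequence they had in common was set against that of all pairs of lines. Their Jaccard index was 0.0302, against a median of 0.0150 over pairs, and had rank 45 among all pairs (exact one-sided p = 0.263). At the Chr10 loss of FNMN0014 from 35.3 to 36.5 Mb the other 18 lines, FNMN0016 among them, lay between 0.00015 and 0.10. The highest index, 0.262, belonged to FNMN0001 and FNMN0005.

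Whether lines with more lost sequence also had more gained sequence was tested over the 19 lines. Lost sequence was summed over lost segments, so most of the Chr09 loss of FNMN0041, which lies above the limit of -0.4, was left out. FNMN0041 had 1.70 Mb in lost segments against 8.7 Mb in events of at least 1 Mb. This holds for all counts and sums of lost segments. Pearson's r was 0.449 (permutation p = 0.0702, adjusted 0.211) and Spearman's rho 0.233 (permutation p = 0.332, adjusted 0.332), so no relation passed the test. Without the 2 lines farthest from the median in lost sequence r was 0.571 (permutation p = 0.0861). Within scanners r was -0.015 over the 8 NimbleGen arrays (permutation p = 0.969) and 0.375 over the 11 Agilent arrays (permutation p = 0.262), and without FNMN0066 and FNMN0077, left out after seeing the data, it was -0.149. The relation of array noise to the number of lost and gained segments did not pass the test either, with r = 0.122 (permutation p = 0.626, adjusted 0.626) and rho = 0.254 (permutation p = 0.294, adjusted 0.332), nor did its relation to homozygous-range sequence, with r = -0.164 (permutation p = 0.546, adjusted 0.626) and rho = -0.419 (permutation p = 0.0751, adjusted 0.225).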

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

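Apart from the test for a wave along Chr09, all tests in this part were chosen after the result was seen. On Chr01 from 20.9 to 28 Mb, FNMN0066 was lost at -0.87 and FNMN0077 gained at 0.56, a difference of -1.44 for FNMN0066 minus FNMN0077; it stands here because the lines moved in opposite directions, and the difference was not tested, since each line has 1 array.

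At 9 short loci on 8 chromosomes, among them Chr12 from 39184790 to 39194269 and Chr15 from 47403135 to 47408029, a loss was called in 18 or 19 lines, with line means from -1.95 in FNMN0036 to -0.63 in FNMN0014. The levels moved in parallel between loci: the mean pairwise Pearson r over lines was 0.971, above the highest of 100000 permuted means, 0.216 (permutation p = 1e-05, the smallest they can give), which argues against separate deletions in each line. The smallest pairwise r was 0.942, as 1 DNA fraction that matches these loci and differs in amount between DNA samples would give. Depth went partly with the scanner. The deepest means, in FNMN0036, FNMN0008 (-1.95), FNMN0005 (-1.86) and FNMN0001 (-1.78), were on NimbleGen arrays, but so was the shallowest. The deepest on an Agilent array was -1.38, in FNMN0048. The mean r was 0.982 within the 8 NimbleGen arrays and 0.939 within the first 7 Agilent arrays. Batch and DNA sample cannot be told apart as the source of the depth. Parental DNA that differs between arrays is argued against at 4 of the loci, both named above among them. There the parent channel varied between arrays under 0.5 times as much as the line channel. Its slope on the log2 ratio was at lowest -0.0973 ± 0.118 (SE), against -1 if that DNA carried the whole difference. A difference between the channels that is the same on every array, in the parental DNA or the dyes, was not tested, as it leaves no slope. Among the 5 other loci the lowest slope was -0.550 ± 0.290 (SE), on Chr14 from 10711249 to 10713528. There parental DNA that differs between arrays stays open. At the rest of these 5 the slopes ran from -0.342 ± 0.199 to -0.157 ± 0.188 (SE). Each lay above -1 by several times its SE, which argues against such DNA carrying the whole difference at these loci. Whether it carried a part there stays open. Over all 9 the ratio of the SDs was 0.596, from 0.189 to 1.10 per locus. No biological explanation was tested, as the labels give each line a group of its own.

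Loci of at most 100 kb were selected that were called in 5 to 17 lines, with at least 3 lines within 0.35 of 0 and a level of at least 1.5 in size in 1 line or more; 4 gained and 3 lost loci passed: Chr18 from 12919304 to 12928851 stood at 4.24 in FNMN0030 and 0.01 in FNMN0022, and Chr18 from 13212555 to 13220257 at -4.12 and -0.0039. Gained and lost here give the direction of the ratio only. A level of 4.24 lies far above the ratio of 1 for 4 copies, and no copy number was derived from it. Reference DNA that differs between arrays is argued against by the parent channel, whose SD between arrays was 0.198 times that of the line channel. Variants standing in the parental stock stay open: 6.02% of the 133 values lay between 25% and 75% of the full level, and 3.17% without FNMN0027, which held 4 of these 8 values, but the loci were selected for lines near 0 and lines far from it, which keeps that share low by itself. Whether the lines had separate events stays open, as the comparison made for it could not decide. Of the calls, 94.7% shared both ends, within 3 probes, with another line, but so did 54.8% of other short calls. The rule for counting this against separate events asked for a share that cannot be reached with 54.8% in the other calls.

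The Chr09 loss of FNMN0041 from 14.2 to 23.5 Mb, at -0.36, lay above the 9 long 1-copy losses, which spanned -0.91 to -0.82. A wave along the chromosome is argued against by the same array, where the lowest of 6900 windows of as many bins on other chromosomes had a median of -0.016 with the other lines subtracted. A patchwork of unchanged stretches and 1-copy losses is argued against too, as 8.43% of the 83 bins lay within 0.2 of 0 or at or below -0.65, and 12.8% of 94 with the separate stretch from 12.9 to 13.5 Mb included, none of them at or below -0.65. A mixture of cells or plants with and without a 1-copy loss may account for it: the SD between bins was at most 0.0918 in both long stretches and 0.151 from 12.9 to 23.5 Mb with the interruptions, against 0.0533 to 0.166 in 8 losses of 1 copy, although this alone does not single out a mixture and leaves the interruptions near 0 unexplained. Homozygous-range losses stood at -5.60 on the FNMN0041 array, against -5.98 to -4.75 in 12 other lines with such losses. A large share of DNA without those losses would have raised that level. This argues against a mixture with plants that lack them, while a mixture of cells or plants that all carry them stays open. The interruption from 19.7 to 20.3 Mb also stood apart from its surroundings in other lines. Gains were called there in 2 lines, from 19772689 to 20080898 with levels up to 0.54 and from 20082761 to 20261948 with levels up to 0.61. Whether this stretch belongs to the loss was not tested.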

How the results depend on the processing

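The large events, the joined losses, the counts without the last scan period, the correlation without FNMN0066 and FNMN0077, the normexp levels of long losses and the sums without single lines were chosen after seeing the data; the gene list comparison and its alternatives were not run. Large events numbered 24 to 27 under 7 alternatives of the processing, which covered 50% or more of the length of 24 of the 26 events with 50 kb bins and of all 26 otherwise, and segments of at least 1 Mb numbered 47 to 58 against 48. Lost sequence stayed between 85.8 and 108 Mb against 92.8, gained sequence between 138 and 155 Mb against 143, and homozygous-range sequence between 35.9 and 41.7 Mb against 37.7, except for 24.7 Mb with normexp. These sums rest on few lines: without FNMN0077 57.1 Mb of gained sequence was left, and without FNMN0065 71.3 Mb of lost and 18.9 Mb of homozygous-range sequence. Counts of short segments moved further, and the cause was not tested except where fewer or more probes, or fewer arrays, were required by construction. With a minimum of 10 probes there were 475 lost, 373 gained and 466 private segments and 59 joined homozygous-range losses; with 3 probes there were 2254 lost, 1410 gained and 1371 private segments. Normexp gave 284 gained, 911 homozygous-range and 472 private segments; the filter on dim probes 338 gained and 386 private; the doubled penalty 337 gained and 406 private; the hidden Markov model 95 homozygous-range losses; subtraction of probe medians 1186 private segments; and any overlap counted as shared 477. Without the 4 arrays of the last scan period 637 lost and 417 gained segments were left, and those 4 arrays had medians of 109 lost (from 103 to 134) and 66 gained segments per line (from 1 to 135) against 50 and 26 over all 19 lines. The correlation of lost with gained sequence, 0.449, was -0.015 on NimbleGen arrays and -0.149 without FNMN0066 and FNMN0077, and 0.528 for numbers of segments (permutation p = 0.0232), where Spearman's rho was 0.061. The likeness of FNMN0014 and FNMN0016 did not pass its test under 4 alternatives. The levels of the deep losses depend on the handling of background. The share of spots well above background in the line channel was lowest in FNMN0030 (98.8%) and FNMN0065 (98.9%). Outside their losses among the 52, the share of probes was 99.2% in FNMN0030 and 99.4% in FNMN0065, so the lower shares go with the lost sequence.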

Other observations

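Inside the Chr01 gain of FNMN0077, 13 of 347 bins lay below 0.2, in 4 stretches of at least 2 bins. These ran from 23.8 to 24.1 Mb at 0.06, from 25.2 to 25.6 Mb at 0.05, from 40.4 to 40.6 Mb at 0.05 and from 47.1 to 47.5 Mb at 0.06. In the Chr01 gains of FNMN0066 longer than 10 Mb, 0 of 136 and 0 of 282 bins lay below 0.2, and in the Chr19 gain of FNMN0077 1 of 470.

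FNMN0061 and FNMN0065 had overlapping losses on Chr14: the FNMN0061 losses from 27365909 to 27486803 at -5.74 and from 32942291 to 33363517 at -5.58 both fell inside the long Chr14 loss of FNMN0065. On Chr04 the 1-copy loss of FNMN0077 from 20.8 to 25.1 Mb covered the homozygous-range loss of FNMN0008 from 21.5 to 22.8 Mb, and on Chr10 the 1-copy losses of FNMN0061 and FNMN0077 overlapped from 23.8 to 25.9 Mb.

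The hypothesis that losses lie in sequence with few probes was written down before its test was run. The 52 joined homozygous-range losses over whose whole length no other line had a median at or below -1.5 held 604 probes per Mb against a median of 1005 over 10000 rotations along the genome (two-sided permutation p = 0.0404, adjusted 0.0560), and the 9 long losses of 1 copy held 558 against 985 (permutation p = 0.0560, adjusted 0.0560). Both lie below 95% of rotated positions, yet neither passes the two-sided test after adjustment. Most of this sequence belongs to a few long losses, so the test rests on few independent positions.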
